A study of Rattus norvegicus with 50 samples.

How the data were processed

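Liver RNA from 50 male Sprague Dawley rats was measured on Affymetrix Rat Gene 1.0 ST arrays, 1 array per animal. The animals formed 10 groups of 5. Intact sham animals were compared with animals that had received a controlled cortical impact, a mechanical contusion of the exposed brain, followed by saline vehicle, erythropoietin (EPO, 2500 IU/kg) or the interleukin-1 receptor antagonist anakinra (100 mg/kg), with livers taken 24 h, 72 h or 7 days after the injury. The tissue came from punches of the median lobe. How often and when the drugs were given, and the time of day of collection, are not given in the sources used here.

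The authors processed the arrays with robust multi-array averaging (RMA) in the oligo package, and the deposited values are log2 RMA values, which are background-corrected, quantile-normalised and summarised per transcript cluster. The versions of both are not given in the sources used here. The values behaved as log2 intensities: the arrays had medians from 6.66 to 6.89 and standard deviations over all probes from 1.99 to 2.16, and no further transformation was applied. Scanner values were not analysed here, so background correction and normalization rest on the authors' processing. The sample labels name a Cy3 dye, which is not the usual label for this platform, and it was not used for anything here. Arrays give no counts, so their number limits the precision, and the table used here held no detection call.

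The table held 29214 transcript clusters, called probes here. Of these, 15310 carried a single gene symbol, 323 several symbols and 13581 none. For each gene the probe with the highest mean was kept, which left 14506 genes, of which 527 had several probes. Probes without a single symbol were left out of the comparisons and tested apart. All genes were kept whatever their intensity. Of the probes matched to the current gene annotation, 99.8% had a current symbol and 0 had a symbol that differed from it.

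Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on a model with 1 mean per group over all 50 arrays and 40 residual degrees of freedom. There were 18 comparisons of 2 groups. The 9 main comparisons were vehicle against sham, EPO against vehicle and anakinra against vehicle at each time, and the 9 others were each drug against sham and EPO against anakinra. There were also 3 F tests, of vehicle over time and of the interaction of each drug with time. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 14506 genes within each comparison, and a gene passed at an adjusted p under 0.05. Standard errors (SE) are the moderated ones of limma. Beside some genes stands the number of the 5 arrays of the first group that lay beyond every array of the second. Log2 differences are the first group minus the second.

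A total of 34 gene lists was fixed before the data were examined, as were the comparisons, the threshold, the genes to be named and the alternatives listed here, except where said otherwise. They covered drug-metabolising enzymes (P450 families 1 to 3, other phase I enzymes, conjugating enzymes), uptake and efflux transporters, xenobiotic and liver transcription regulators, bile acid genes, positive and negative acute phase proteins, targets of IL-1, TNF and NF-kB, interferon response, erythroid and blood transcripts, iron and BMP-SMAD handling, STAT5 and cytokine-receptor feedback, male-biased and female-biased rat liver genes, the circadian clock, glucocorticoid response, fatty acid oxidation and synthesis, cholesterol synthesis, ER stress, heat shock proteins, oxidative stress and NRF2 targets, cell cycle, ribosomal proteins, oxidative phosphorylation, and markers of Kupffer cells, neutrophils, lymphocytes, liver endothelium, stellate cells, cholangiocytes and neighbouring tissues (pancreas, muscle, adipose and mesothelium). Of the members given, 86.3% were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Beside it stand camera with the correlation estimated from the residuals, and fry, which tests whether the genes of a list move on balance in 1 direction. Counts adjusted over the list alone are given beside the counts adjusted over all genes.

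The genes named were, for the main comparisons, the 8 with the highest and the 8 with the lowest log2 difference among those that passed, and up to 4 members of each list with the smallest p among those that passed. Where fewer than 16 genes passed, the 5 with the smallest p that did not pass were named too. For the other comparisons the rule took the 5 highest and 5 lowest, and for the F tests the 10 with the smallest p. It also took 32 drug-metabolism, transport, acute phase and drug-target genes whatever they showed, of which 29 were measured. The text gives those that carry each comparison and summarises the rest.

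The alternatives were array weights, a model with eBayes trend and robust options, only the groups compared in the fit, the dimmest 33.3% of genes left out (9671 left), the mean of all probes of a gene, all probes of the table, a second quantile normalization, each array shifted to a common median, the replicate number as a block, a change of at least 1.5-fold, each array left out in turn, and the control arrays split into parts of 2 and 3 for the correlations between effects. Background correction and a block for slide or scan date were listed too and were not run, since neither scanner values nor dates were in the files used here. Chosen after seeing the data were a fit without 5 arrays whose standard deviation lay more than 3 median absolute deviations below the median of all arrays, and a fit with that standard deviation as a covariate. The replicate numbers were tested as a pairing of animals: residuals of arrays with the same number had a mean correlation of 0.0125, so the numbers were not used as pairs. The procedure was tested on simulated data with 50 genes changed in each of several steps: it recovered 62% of those changed by 0.5 log2 and 100% of those changed by 1, with 5 arrays per group. The simulated noise was independent for each gene and array, without arrays of lower standard deviation, so these shares can be too high for the real data. A gene that did not pass may still have changed by more than 1: Scd differed by -1.35 between vehicle livers at 72 h and sham (adjusted p = 0.396 in limma).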

Results

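Liver transcripts were measured in 50 rats, 5 in each of 10 groups. There was 1 group of intact sham animals. The other 9 had a controlled cortical impact of the brain, received saline vehicle, EPO (the growth factor of red blood cell precursors) or anakinra (an antagonist of the interleukin-1 receptor), and had their livers taken 24 h, 72 h or 7 days later. The title of the series gives the aim, the effect of brain injury and of both drugs on hepatic metabolising enzymes and transporters. All values are log2 RMA values, and 14506 genes were tested. Array medians lay between 6.66 and 6.89. The standard deviation over all probes was 2.11 in the median array and lay below the rest in 5 arrays, called narrow arrays here. They were vehicle array 3 at 24 h (1.99), vehicle arrays 2 (1.99) and 5 (2.03) at 72 h, vehicle array 3 at 7 days and EPO array 3 at 7 days (2.04). Of these, 4 were in vehicle groups, which enter every comparison of a drug with vehicle. Genomic positions of the probes are not given in the sources used here.

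**Figure D1:**
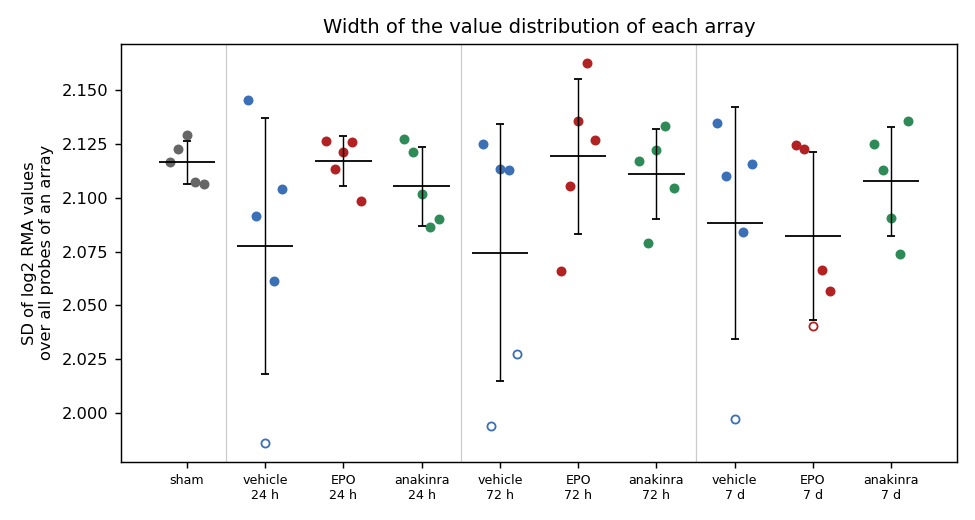
Standard deviation of the log2 RMA values over all probes of each array (y axis, log2 units) by group (x axis); each point is 1 array, open points are the 5 narrow arrays, and lines and bars are the mean and SD of the 5 arrays of a group. The narrow arrays lay between 1.99 and 2.04, against a median of 2.11 over all 50 arrays.

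Vehicle-treated injured livers were compared with sham livers to see how they differed from those of intact animals. The same sham group served for all times, and its labels give neither a time nor a vehicle. Injury can therefore not be told apart from the saline, the handling or the time of collection. At 24 h 8 of 44 acute phase and 5 of 23 cholesterol synthesis genes were higher in the injured livers and 7 of 46 cell cycle genes lower, and with all arrays none of these lists was called with an estimated correlation (adjusted p = 0.170, 0.170 and 0.142). Lbp (probe 10841693), the lipopolysaccharide-binding protein secreted by hepatocytes, was 11.52 ± 0.12 in sham and 12.45 ± 0.09 in injured livers (mean ± SD, n = 5 each), 1.91-fold higher. Sqle (10896772), squalene epoxidase of the cholesterol pathway, was 2.20-fold higher, and Ccnd1 (10727260), cyclin D1, was 2.30-fold lower. Il1r1 (10922826), the receptor that anakinra blocks, rose by 0.93 log2 (SE 0.16, adjusted p = 0.00192), with 5 of 5 injured arrays above every sham array.

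Of the 44 measured positive acute phase proteins, 8 rose and 0 fell (16 and 1 adjusted over the list alone). Among them were Lbp (0.93 log2, adjusted p = 0.0122), Fgl1, a hepatocyte-secreted fibrinogen-like protein (0.72), Stat3, the transcription factor of the interleukin-6 pathway (0.68), and Kng1, kininogen (0.47), each higher in 5 of 5 arrays. The list was called (camera adjusted p = 3.47e-07, 0.170 as adjusted p with an estimated correlation, and 0.0265 so estimated without the narrow arrays). Of the 23 cholesterol synthesis genes, 5 rose (12 over the list alone), among them Hsd17b7 (0.97), Lss, lanosterol synthase (0.76), and Srebf2, the transcription factor that drives the pathway (0.60). Its member Idi1, of isoprenoid synthesis, rose by 1.01 (adjusted p = 0.0471). The list's call (1.78e-10) had an adjusted p = 0.170 with an estimated correlation, and 0.0207 without the narrow arrays.

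Of the 46 cell cycle genes, 7 fell and 0 rose (17 lower over the list alone): Ccnd1 (-1.20), Rrm2, a subunit of ribonucleotide reductase (-1.04), and Cdkn3 (-0.83). The list was called lower (3.12e-11), with an adjusted p = 0.142 with an estimated correlation and 0.0207 without the narrow arrays. Of the 21 clock genes, Dbp (1.58), Per3 (1.13) and Tef (0.64) rose and Bmal1 (-0.70) fell. The clock list as a whole, whose members go both ways, was not called (0.705). Of the 37 iron genes 5 rose, with Tfr2, transferrin receptor 2 (0.47), Slc39a14, an iron and zinc importer (0.51), and Cp, ceruloplasmin (0.33). This list was not called either (0.782). Derl3 of the ER stress list rose by 1.23 and the citrate transporter gene Slc13a5 by 1.53. The lowest difference was that of Scd, stearoyl-CoA desaturase, which fell by 2.22 (SE 0.57, adjusted p = 0.0441, 4 of 5 arrays). Besides Ccnd1 and Rrm2, the genes that fell included Akr7a3, an aldehyde reductase (-1.56), Cdkn1a (-1.09), Car1, a carbonic anhydrase abundant in red cells (-1.08), the taurine transporter Slc6a6 (-1.07) and the chemokine gene Cxcl9 (-1.02).

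In all, 54 genes were higher and 66 lower at 24 h (2310 at an unadjusted p under 0.05, with 725.3 expected by chance). Leaving out 1 array gave 63, 58, 75 and 64 genes without sham array 2, 3, 4 or 5, and 56 and 74 without vehicle array 3 or 4. Array weights gave 267 genes, and the fit without the narrow arrays gave 79, of which 69 were among the 120. Of the 45 genes named by the rule, 23 passed whichever array was left out, among them Lbp, Il1r1, Dbp, Per3, Hsd17b7, Lss, Ccnd1 and Rrm2. The call ended for Scd and Idi1 without any array but vehicle array 1 (adjusted p up to 0.150 and 0.132). It ended for Bmal1 without any sham array or vehicle array 2, 3 or 5 (up to 0.102) and for Slc6a6 without any sham array or vehicle array 2 or 5 (up to 0.135). The same held for Cdkn1a without sham array 2 or 3 or vehicle array 3 or 5 (up to 0.135), Cxcl9 without sham array 4 or 5 or vehicle array 3 (up to 0.0992) and Cdkn3 without sham array 5 (0.0968). Sqle lost its call without sham array 3 or vehicle array 4 (up to 0.0550) and Cp without sham array 2 or vehicle array 4 (up to 0.0953). Without the narrow arrays Scd, Cdkn1a and Cxcl9 did not pass (0.0672, 0.0573 and 0.0838).

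**Figure D2:**
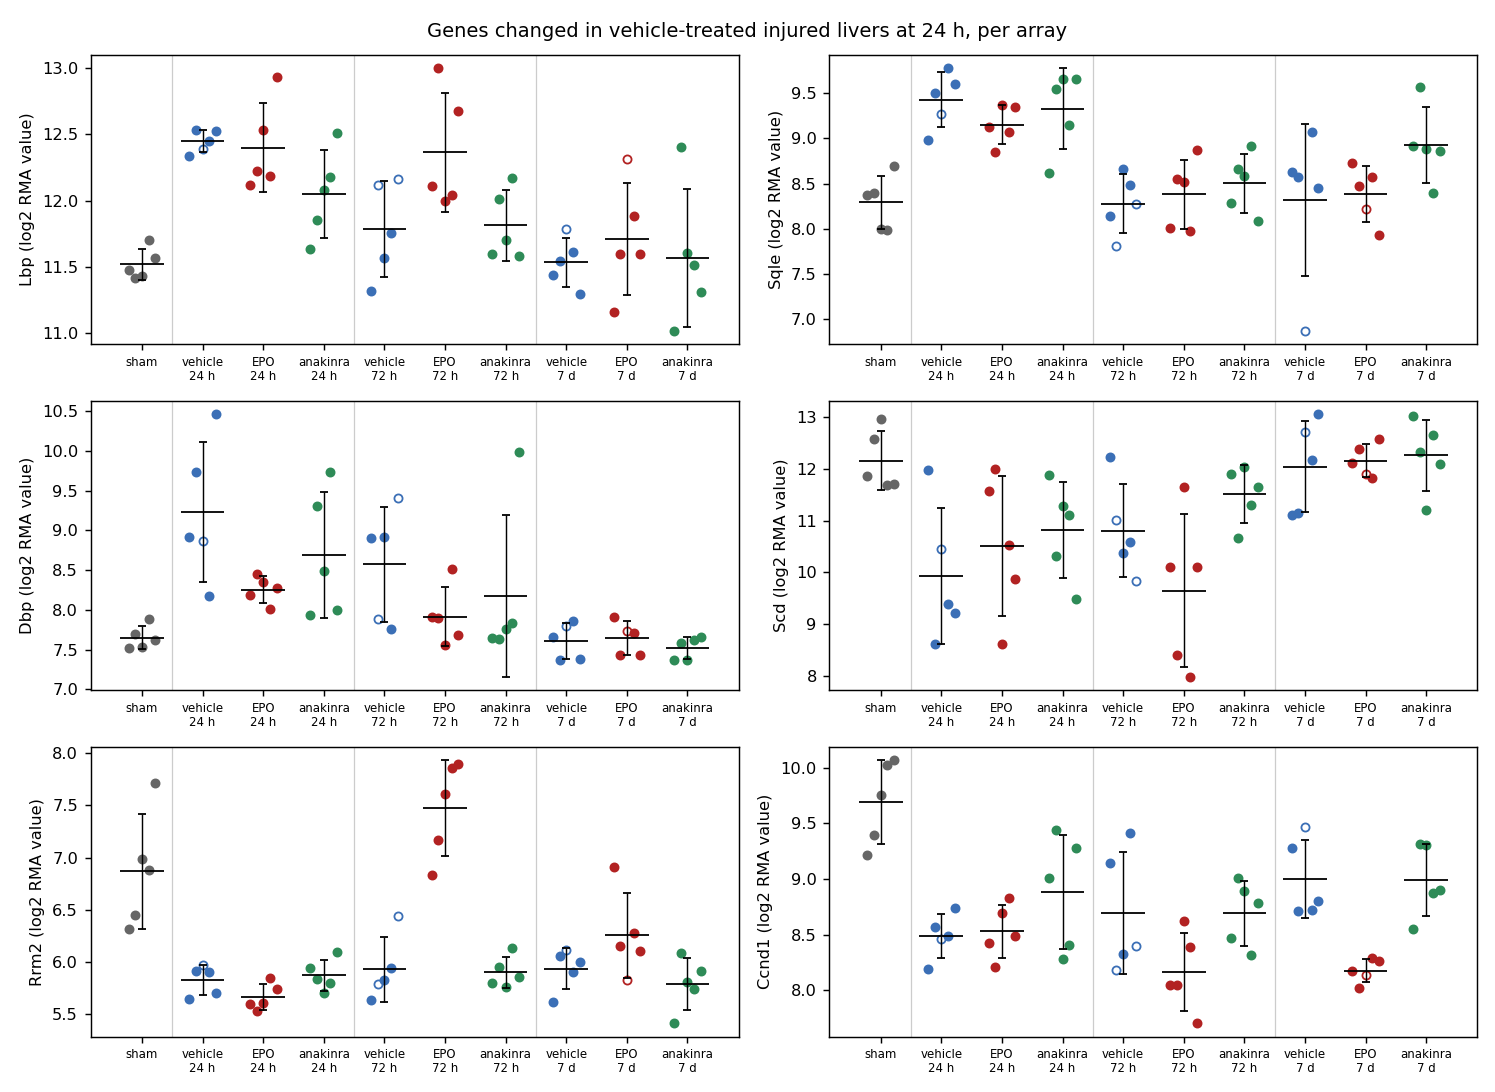
Log2 RMA values (y axes) of Lbp, Sqle, Dbp, Scd, Rrm2 and Ccnd1 in each array by group (x axes); points are arrays, open points are the narrow arrays, and lines and bars are the mean and SD of the 5 arrays of a group. Mean Rrm2 was 6.87 in sham livers, 5.82 in vehicle livers at 24 h and 7.47 in EPO livers at 72 h.

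At 72 h and 7 days no gene passed between vehicle and sham livers. At 72 h limma called 0 genes (1757 at an unadjusted p under 0.05, 5 with array weights). The smallest p-values belonged to Rrm2 (-0.94, 4 of 5 arrays below every sham array) and Rbp7, a retinol-binding protein (-0.57, 5 of 5), both with an adjusted p of 0.0668. C2h4orf46 (-0.77), Ccnd1 (8.69 against 9.69 in sham) and Rarres1 (-0.69) followed at 0.0724, and none of them passed. At 7 days it called 0 genes (946 at an unadjusted p under 0.05, 2 with array weights). Rrm2 came first (-0.93, adjusted p = 0.121), then Slc35a4 (-0.52), Cdkn3 (-0.84), Tacr1 (0.55) and Vom1r49 (0.43), which did not pass. At 72 h 3 genes passed without sham array 1, 1 without sham array 2, 5 without vehicle array 1 or 4, and 1 without vehicle array 5. At 7 days 2 and 1 passed without sham array 1 or 2.

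The cell cycle list was called lower at both times (1.42e-07 and 2.17e-13; adjusted p = 0.263 and 0.115 with an estimated correlation, and 0.0201 and 0.0283 without the narrow arrays). Of its 46 genes 5 and 11 were lower over the list alone and 0 over all genes. At 7 days the heat shock proteins were also called lower, with a median of -0.33 and 7 of 19 genes lower over the list alone (9.60e-13; adjusted p = 0.115 with an estimated correlation). Oxidative phosphorylation genes were called lower at 72 h (median -0.19, 1.38e-11; adjusted p = 0.263 with an estimated correlation). Ribosomal protein genes were too (median -0.11, 0.000191; adjusted p = 0.674 with an estimated correlation). The call of the ribosomal list ended without the narrow arrays (0.715 at 72 h and 0.0524 at 24 h), and that of oxidative phosphorylation at 72 h did not (0.000657).

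The F test over the 3 vehicle groups found 10 genes that differed between times (776 at an unadjusted p under 0.05): Adamts9, Derl3, Hsd17b7, Slc17a3, Prxl2b, Gckr, Per3, Npas2, Sqle and Ces2c. Most of them were away from sham at 24 h and near it later. Derl3 was 1.23 log2 above sham at 24 h, 0.03 at 72 h and 0.04 at 7 days (adjusted p = 0.00363), Sqle 1.14, -0.02 and 0.03 (0.0329), and Npas2, a clock transcription factor, -0.84, -0.05 and 0.36 (0.0305). Without vehicle array 2 or 5 at 24 h the count was 5 and 4, and without vehicle array 5 at 7 days it was 5. Without the narrow vehicle array 3 at 24 h it was 18, and without the narrow vehicle array 5 at 72 h it was 23.

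EPO was compared with vehicle at each time to see what the drug changed in the injured animal. At 24 h, 4 genes were higher and 0 lower in EPO livers (1572 at an unadjusted p under 0.05). Egr1 (10800919), an immediate-early transcription factor, was higher by 1.13 log2 (SE 0.22, adjusted p = 0.0285) and Fgf23 (10859003), a phosphate-regulating hormone, by 0.81 (0.0117). Dmbt1, a secreted scavenger-receptor protein on the cholangiocyte list, was higher by 0.78 (0.0285) and Csf2rb, the common beta chain of cytokine receptors, by 0.60 (0.0285). Each was higher in 5 of 5 arrays. The next smallest p-values did not pass and belonged to Tacr1 (0.63), Hist1h4b (0.56), the neutrophil collagenase gene Mmp8 (0.88), Il18 (0.60) and Hnf4g (0.88), with adjusted p-values from 0.0650 to 0.189. Hamp, which encodes hepcidin, the hormone that blocks iron export into plasma, differed by -1.80 (SE 0.44, adjusted p = 0.189) from vehicle. In a fit of only the groups compared 0 genes passed, and without the narrow arrays 2 did, with Dmbt1 at 0.245 and Csf2rb at 0.229. The count was 1 without vehicle array 3 or 4 or EPO array 1, 2 without EPO array 3 or 4, and 0 without vehicle array 5 or EPO array 5. The call of Egr1 ended without vehicle array 1, 3, 4 or 5 or EPO array 1, 3 or 5 (adjusted p up to 0.195) and that of Fgf23 without vehicle array 5 or EPO array 5 (up to 0.0873). That of Csf2rb ended without any array but vehicle array 1 and EPO arrays 2 and 3 (up to 0.233), and that of Dmbt1 without any array but vehicle arrays 1 and 2 (up to 0.288).

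At 72 h EPO livers carried far more erythroid transcripts and far less hepcidin transcript than vehicle livers. Alox15 (10744425), a 15-lipoxygenase that breaks down organelles in maturing red cells, was 12.73 ± 0.58 in EPO and 8.89 ± 1.61 in vehicle livers, a rise of 3.84 log2 (SE 0.55). Ahsp (10711396), the chaperone of alpha globin, was 13.2-fold higher, and Slc4a1, the band 3 anion exchanger of the red cell membrane, was 7.43-fold higher. Hamp (10720829) was 12.01 ± 1.45 in vehicle and 8.21 ± 0.88 in EPO livers (mean ± SD, n = 5 each), 13.9-fold lower (adjusted p = 4.67e-08, 5 of 5 arrays). The neutrophil collagenase gene Mmp8 was higher by 2.23 log2 (SE 0.20), Rrm2 by 1.55 (SE 0.19) and Csf2rb by 1.32 (SE 0.12), each in 5 of 5 arrays.

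Of the 24 erythroid and blood transcripts, 17 rose and 0 fell (21 and 1 over the list alone). Among them were Rhag (4.01-fold) and Rhd (2.42 log2), of the Rh blood group complex, Slc25a37, the mitochondrial iron importer (1.36), Epb42 (1.76), and Alas2, which starts heme synthesis in red cell precursors (1.94, adjusted p = 0.0106). Hemgn, a nuclear protein of red cell precursors, rose by 2.28. The list was called (1.17e-33) and kept its call with an estimated correlation (adjusted p = 0.00847). Of the 46 cell cycle genes 14 rose (22 higher and 1 lower over the list alone), among them Cdkn3 (0.91), Ccna2 (0.53) and Kif11 (0.47); the list kept its call with an estimated correlation (adjusted p = 0.0300). The mean of this list was 0.29 above vehicle (95% interval 0.18 to 0.39) and 0.11 above sham (-0.00 to 0.21). Of the 25 Kupffer cell and macrophage markers 14 rose (20 and 1 over the list alone). The heme oxygenase gene Hmox1 rose by 0.84 in 5 of 5 arrays, Cd163, the haptoglobin-hemoglobin scavenger receptor, by 0.78 with 2 of 5 arrays above every vehicle array, and Vsig4 by 0.76 in 4 of 5. This list also kept its call (adjusted p = 0.0351 with an estimated correlation, 0.00492 without the narrow arrays).

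Of the 21 neutrophil markers 7 rose (9 over the list alone), among them Mmp8, Ngp (1.84), S100a9 (1.37) and S100a8 (0.71), with an adjusted p = 0.122 with an estimated correlation. Of the 29 lymphocyte and NK cell markers 3 rose, given here outside the naming rule and chosen after their values were seen: Il7r (0.97), Gzma (0.61) and Nkg7 (0.53), with 4, 4 and 1 of 5 arrays above every vehicle array. The list was not called (0.345). The call of Gzma ended without vehicle array 1 or 2 or EPO array 2, 3 or 4 (adjusted p up to 0.120) and that of Nkg7 without vehicle array 1, 2 or 3 or EPO array 2, 3 or 4 (up to 0.180). Of 19 liver endothelial markers 5 rose (9 over the list alone), such as Tie1 (0.42) and Oit3 (0.47), with an adjusted p = 0.0823 with an estimated correlation. Of 44 positive acute phase proteins, the cytokine receptor gene Osmr rose by 0.94 with 1 of 5 arrays above every vehicle array, and Hamp, which the list also holds, fell (13 higher and 1 lower over the list alone). The call of this list (3.14e-07) had an adjusted p = 0.111 with an estimated correlation. Of the 32 STAT5 genes Csf2rb and Pim1 (0.77) rose (3 over the list alone; camera 0.0141, adjusted p = 0.0704 with an estimated correlation). Of the 37 iron genes 4 rose and 2 fell, with Cd163, Hmox1 and Ncoa4, the receptor for ferritin turnover (0.68), among the first and Hamp among the second. Further genes that rose were Emb (2.67), the interferon-induced Rsad2 (2.38) and the amino acid response gene Asns (2.08). Rsad2 was the only member of the interferon response list that passed there, and Asns the only member of the ER stress list. The mitochondrial carrier Ucp2 (1.52), the fatty acid receptor Cd36 (2.83-fold) and the growth factor Hgf, on the stellate cell list (0.64), rose too. Apart from Hamp, the lowest of the genes that fell were Cbln3 (-0.61), Wfdc18 (-0.52), Lin28a (-0.51), Or4a66b (-0.50) and Id2 (-0.48).

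In all, 316 genes were higher and 79 lower (2908 at an unadjusted p under 0.05), of which 154 and 2 changed at least 1.5-fold. The fit of only these 10 arrays called 53. Leaving out 1 array gave 205 without vehicle array 2, 785 without vehicle array 4, 1520 without EPO array 1 and 246 without EPO array 2. Of the 54 genes named by the rule, 37 passed whichever array was left out and 44 without the narrow arrays. The call of Alas2 ended without vehicle array 1 or 2 or EPO array 4 (adjusted p up to 0.0831) and without the narrow arrays (0.0889). The call of Osmr ended without vehicle array 1, 2 or 3 or EPO array 2 (up to 0.191) and that of Id2 without vehicle array 1, 4 or 5 or EPO array 1 or 4 (up to 0.122). Lin28a lost its call without vehicle array 1, 2 or 5 or EPO array 2, 4 or 5 (up to 0.129), Oit3 without vehicle array 2 (0.0519), and Cbln3 without vehicle array 1 (0.0633). Without the narrow arrays Lin28a and Or4a66b did not pass (0.229 and 0.0544).

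**Figure D3:**
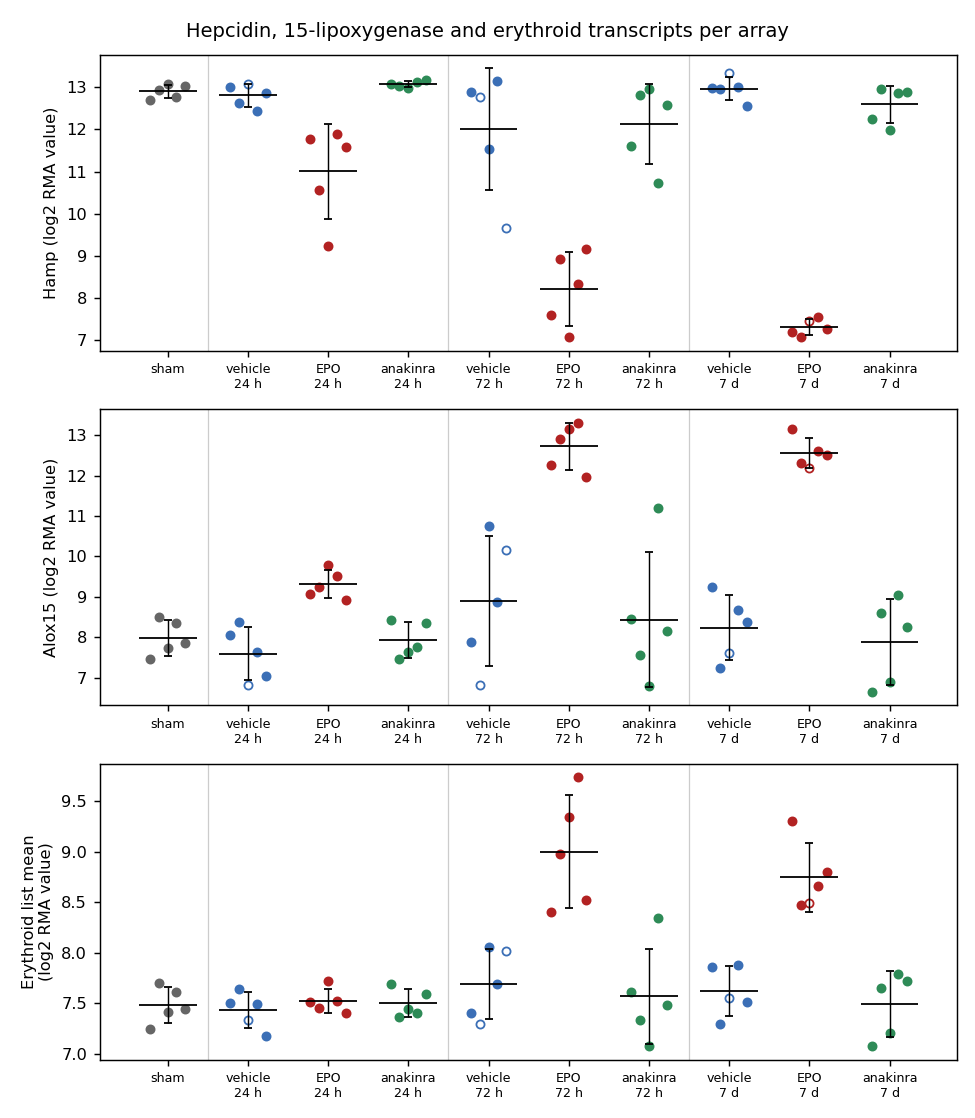
Log2 RMA values of Hamp and Alox15 and the mean log2 RMA value of the 24 measured erythroid and blood transcripts (y axes) in each array by group (x axes); points are arrays, open points are the narrow arrays, and lines and bars are the mean and SD of the 5 arrays of a group. Mean Hamp was 12.90 in sham livers and 11.01, 8.21 and 7.31 in EPO livers at 24 h, 72 h and 7 days.

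At 7 days the drop in hepcidin transcript was deeper and the erythroid transcripts were still high. Hamp was 12.97 ± 0.28 in vehicle and 7.31 ± 0.19 in EPO livers (mean ± SD, n = 5 each), 50.7-fold lower (adjusted p = 6.58e-13, 5 of 5 arrays). Alox15 was 20.0-fold higher and Ahsp 10.2-fold higher. Of the 24 erythroid transcripts 14 rose (20 and 1 over the list alone), with Slc4a1 (2.48), Rhd (2.40), Hemgn (2.08), Alas2 (2.17, SE 0.47, adjusted p = 0.0118) and Slc25a37 (1.23). The list kept its call with an estimated correlation (adjusted p = 0.000251). In the iron list, Tfrc, the transferrin receptor through which cells take up iron, rose by 1.22 (SE 0.22, 5 of 5 arrays) and Ncoa4 by 0.64.

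Rsad2 (2.28), Cd52 (2.05), Ucp2 (1.30) and Cd36 (1.14) were higher as well, each in 5 of 5 arrays, and the glutathione transferase gene Gsta3 was higher by 0.72 (adjusted p = 0.0478, 4 of 5). Of the 46 cell cycle genes and the 21 neutrophil markers 0 passed in limma. The means of these lists differed from vehicle by 0.05 (95% interval -0.05 to 0.16) and by 0.01 (-0.16 to 0.17). Besides Hamp, 4 genes fell: Pfkfb1 (-0.87), the acyltransferase gene Acnat2 (-0.38), Zmiz2 (-0.38) and Apoa5, an apolipoprotein of triglyceride metabolism (-0.35). The glucocorticoid response and gluconeogenesis list was called lower (median -0.18, 1.87e-06; adjusted p = 0.484 with an estimated correlation), with Pfkfb1 its 1 gene that passed. In all 48 genes were higher and 5 lower (721 at an unadjusted p under 0.05), and 34 passed without EPO array 1. Of the 19 genes named by the rule, 13 passed whichever array was left out. The call of Alas2 ended without vehicle array 2 or EPO array 1 (adjusted p up to 0.0882) and without the narrow arrays (0.0514). The call of Ncoa4 ended without vehicle array 3 or EPO array 1 or 5 (up to 0.170) and that of Apoa5 without vehicle array 1, 2 or 3 or EPO array 1, 2 or 4 (up to 0.0973). Pfkfb1 lost its call without any array but vehicle array 4 and EPO array 2 (up to 0.177), Gsta3 without any array but vehicle array 2 and EPO arrays 4 and 5 (up to 0.390), and Zmiz2 without any array but vehicle array 2 (up to 0.262). Without the narrow arrays these 3 did not pass (0.185, 0.195 and 0.285).

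The effect of EPO differed between times in 31 genes (interaction of EPO and time, 1228 at an unadjusted p under 0.05). The log2 difference from vehicle at 24 h, 72 h and 7 days was 0.88, 2.23 and 0.22 for Mmp8 (10907913), -0.16, 1.55 and 0.32 for Rrm2 (10883903), and -1.80, -3.80 and -5.66 for Hamp, with adjusted p-values of 7.42e-05, 0.000450 and 0.00120. Rhag (10926769) had the smallest adjusted p, 7.04e-06. Rhag, Ngp, Csf2rb, Fgf23 and Tacr1 also had their highest difference at 72 h, while Cd52 (-0.05, 1.84 and 2.05) and Slc25a37 (0.18, 1.36 and 1.23) were high at both later times. Without EPO array 1 at 72 h the test found 87 genes, and array weights gave 111.

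Anakinra was compared with vehicle at each time to see what blocking the interleukin-1 receptor changed. No gene passed at 24 h or 72 h and 2 passed at 7 days. Stk38l (10859660), a protein kinase gene, rose by 0.53 (SE 0.10) and Vom2r16, a vomeronasal receptor gene, fell by 0.79 (SE 0.15), both with an adjusted p = 0.0342 and in 5 of 5 arrays. Il1r1 itself differed from vehicle by -0.24 at 24 h, -0.01 at 72 h and 0.23 at 7 days, none of which passed. At 24 h limma called 0 genes (616 at an unadjusted p under 0.05, 0 with array weights). Il21r (-0.31), Cyria (0.51), Med20 (-0.35), Inha (-0.34) and Gucy1a1 (-0.22) had the smallest p-values, none of which passed (adjusted p = 0.901). At 72 h it called 0 genes (1546 at an unadjusted p under 0.05, 0 with array weights). Bcl2l11, a gene of programmed cell death, differed by 0.69 in 5 of 5 arrays. Gramd2b (0.51), Tnni2 (-0.39), Spata2L (-0.51) and Vip (-0.40) followed, none of which passed (0.316 to 0.325). At 7 days Hdhd3 (0.53), the cholesterol transporter gene Npc1 (0.41), Apoa5 (-0.36), Pja2 (0.34) and Rasl10a (-0.33) came next and did not pass (0.0994 to 0.123).

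The number of genes at 7 days (1106 at an unadjusted p under 0.05) was 0 without vehicle array 1, 2, 3 or 4, without anakinra array 3 or without the narrow arrays, and 1 without anakinra array 1, 2 or 4; array weights gave 20. The call of Stk38l ended without vehicle array 1 to 4 or anakinra array 2, 3 or 4 (adjusted p up to 0.240) and that of Vom2r16 without vehicle array 1 to 4 or anakinra array 1, 3 or 5 (up to 0.222). Gene lists gave more calls: camera called 13, 15 and 8 of 34 at the 3 times, against 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. At 7 days the cholesterol synthesis genes had a median of 0.24, with 4 of 23 higher over the list alone and 0 over all genes (camera adjusted p = 1.35e-11, and 0.470 with an estimated correlation). One vehicle array lowered the vehicle side: the mean of this list was 9.11 in the narrow vehicle array 3 and 9.96 in the next lowest vehicle array. At 24 h the P450 list had a median of 0.06 and 0 of 36 genes passed (0.000265; adjusted p = 0.319 with an estimated correlation). Without the narrow arrays 8, 7 and 5 lists were called. The interaction of anakinra and time called 0 genes in limma (402 at an unadjusted p under 0.05, 0 with array weights). Vom2r16, Myadm and Ndufb11 came first, none of which passed (adjusted p = 0.405).

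Drug-metabolising enzymes and transporters are the subject of the series title. Of 21 such genes chosen by name (Cyp1a2, Cyp2b1, Cyp2b2, Cyp2c11, Cyp2d1, Cyp2e1, Cyp3a2, Cyp3a18, Cyp7a1, Ugt2b1, Sult1a1, Slco1b2, Slc10a1, Abcb1a, Abcb1b, Abcb11, Abcc2, Abcg2, Por, Nr1i2 and Nr1i3), 0 passed in limma in any of the 9 main comparisons. The smallest adjusted p was 0.153, for Abcc2 in EPO against vehicle livers at 72 h, and the largest difference was -1.22 for Cyp2b1 in vehicle against sham livers at 72 h (0.396). Of the 36 P450 genes 0 passed in these comparisons. The members of the other enzyme and transporter lists that did pass were, at 24 h in vehicle against sham livers, Akr7a3 (-1.56), the epoxide hydrolase gene Ephx1 (-0.70), the carboxylesterase genes Ces2c (0.75) and Ces1f (-0.51), the glutathione transferase genes Gstm1 (-0.35) and Gstm4 (-0.46), and the sterol exporter gene Abca1 (0.39). In EPO against vehicle livers they were Slc28a1 (-0.28) and Abcg1 (0.38) at 72 h and Gsta3 at 7 days. The conjugating enzymes as a list were called lower at 24 h in vehicle against sham livers (median -0.18, 12 lower and 1 higher of 39 over the list alone; adjusted p = 0.121 with an estimated correlation and 0.0429 without the narrow arrays). The call of Ephx1 ended without vehicle array 3 (adjusted p = 0.0543) and that of Ces2c without sham array 5 or vehicle array 2 or 3 (up to 0.104). Ces1f lost its call without any array but sham array 1 and vehicle arrays 4 and 5 (up to 0.0958) and without the narrow arrays (0.0659), Abcg1 without vehicle array 2 (0.0553), and Slc28a1 without vehicle array 1 or 2 or EPO array 2, 4 or 5 (up to 0.150) and without the narrow arrays (0.139).

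Against sham livers, and against anakinra livers, the P450 and conjugating enzyme lists were called lower in EPO livers at 72 h. In these comparisons markers of other cell types were higher: 19 and 20 of 24 erythroid transcripts (21 and 21 over the list alone), 8 and 8 of 21 neutrophil markers (11 and 11) and 9 and 4 of 25 Kupffer cell markers (20 and 15). These 3 lists were called in both with an estimated correlation (adjusted p up to 0.0440). The P450 list had medians of -0.16 and -0.14 (adjusted p = 0.0440 and 0.00585 with an estimated correlation). Against sham 3 of 36 P450 genes fell (7 lower and 1 higher over the list alone): Cyp2d4 (-0.83), Cyp2b12 (-0.31) and Cyp2j3 (-0.39). In EPO against anakinra livers 3 were lower (8 lower and 1 higher over the list alone): Cyp2b2 (10705230), a barbiturate-inducible P450, by 1.43 (SE 0.38, adjusted p = 0.0337, 4 of 5 arrays), Cyp2a2 (-0.24) and Cyp2b12 (-0.30). Against vehicle at 72 h Cyp2b2 differed by -0.59 in EPO and 0.84 in anakinra livers, neither of which passed. In anakinra against vehicle livers at 72 h the P450 and conjugating enzyme lists were themselves called higher, with medians of 0.11 and 0.05. Their camera adjusted p was 0.000172 and 0.00301, and 0.450 and 0.608 with an estimated correlation. A difference between EPO and anakinra livers can therefore lie on either side. Of 39 conjugating enzymes 8 fell against sham (14 lower and 2 higher over the list alone), with Inmt (-2.36), Nat8 (-1.06), Ugt2a3 (-0.95) and Gstk1 (-0.65), and 3 against anakinra, Mgst2 (-0.45), Gstm7 (-0.37) and Gstm2 (-0.31). This list kept its call in both (adjusted p = 0.0237 and 0.0305 with an estimated correlation), and also in EPO against sham livers at 24 h (2 of 39 lower, 6 over the list alone; 0.0468). The other phase I enzymes were called lower with an estimated correlation against anakinra at 72 h (median -0.14, adjusted p = 0.0329). The male-biased liver genes were called lower against sham and anakinra at 72 h (3 and 2 of 16 lower, 5 and 2 over the list alone; adjusted p = 0.0440 and 0.0305 with an estimated correlation). The female-biased ones were called higher at 24 h against sham in EPO and anakinra livers (medians 0.22 and 0.31; adjusted p = 0.0204 and 0.0165 with an estimated correlation). Of the 16 male-biased and 13 female-biased genes measured, 10 and 7 were shared with another list, so these calls are not separate from those of the other lists. The efflux transporters Abcg1 (0.46), Abca1 (0.39) and Atp8b1 (0.51) rose against sham. In EPO against vehicle livers at 72 h neither enzyme list was called (camera adjusted p = 0.143 for P450 and 0.0886 for conjugating enzymes). Without the narrow vehicle arrays both were called lower there (0.00463 and 0.000251, and adjusted p = 0.197 and 0.134 with an estimated correlation). Other members that passed against sham are given here outside the naming rule and were chosen after their values were seen. They were Mgst2 (-0.50) and Slco2a1 (0.39) in EPO livers at 24 h, and Cyp2j3 (-0.45), Cyp2d4 (-0.68), Slc22a8 (-0.57), Abcc3 (0.33) and the glucocorticoid receptor gene Nr3c1 (-0.64) in EPO livers at 7 days. In anakinra livers the nuclear receptor gene Nr5a2 rose at 24 h (0.37), 72 h (0.41) and 7 days (0.41). These differences hold injury and drug together. In vehicle livers Nr5a2 differed from sham by 0.23, 0.19 and 0.21 at the same times, and Nr3c1 by -0.52 at 7 days. Nr5a2 in anakinra livers and Nr3c1 in EPO livers at 7 days did not pass against vehicle.

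Each drug group was also compared with sham, which puts injury and drug together; these 6 comparisons share the same 5 sham arrays. At 24 h acute phase proteins were higher and cell cycle genes lower in EPO livers (8 higher and 1 lower of 44, and 7 lower of 46; adjusted p = 0.00186 for both with an estimated correlation) and in anakinra livers (3 acute phase genes higher and 3 cell cycle genes lower; 0.0165 and 0.00875). Over the lists alone 22 acute phase genes were higher and 17 cell cycle genes lower in EPO livers, and 15 and 15 in anakinra livers. Cholesterol synthesis genes were higher in anakinra livers (2 of 23, 14 over the list alone; 0.0165), with Hsd17b7 (0.84) and Lss (0.78), and Socs3, a feedback inhibitor of cytokine signalling, rose by 0.94 there. Il1r1 rose by 0.69 (SE 0.16, adjusted p = 0.0472). In EPO livers at 24 h Wfdc21 (1.57), Slc13a5 (1.34), Derl3 (1.10), Mmp8 (0.99) and Egr1 (0.95) had the highest differences, and Hamp fell by 1.90 (SE 0.44, adjusted p = 0.0279, 5 of 5 arrays). Rrm2 fell by 1.21 in EPO livers at 24 h, and in anakinra livers at 24 h (5.87 against 6.87 in sham), 72 h (-0.97) and 7 days (-1.08). Ccnd1 fell in EPO livers at the 3 times (-1.16, -1.53 and -1.52) and in anakinra livers at 72 h (8.69 against 9.69 in sham).

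At 72 h Hamp (-4.69) and Scd (-2.51) fell in EPO livers, Alox15 rose by 4.74 and Il1r1 by 0.74. There 8 of 21 neutrophil markers rose (11 over the list alone; adjusted p = 0.0237 with an estimated correlation). In anakinra livers Fam13a (1.09) and the clock repressor gene Cry2 (0.72) rose and Angptl4, an inhibitor of lipoprotein lipase, fell by 1.65. At 7 days Hamp (-5.59), Pfkfb1 (-1.31) and Mcm10, a DNA replication factor (-1.27), fell in EPO livers, while Alox15 rose by 4.57. In anakinra livers Mybl1 (1.57), Fam13a (1.10) and Cry2 (0.81) rose. Socs2, an inhibitor of growth hormone signalling (-1.71), Sds, serine dehydratase of gluconeogenesis (-1.62), Angptl4 (-1.44) and Rgs16 (-1.12) fell. Heat shock proteins were lower at 7 days in EPO livers (5 of 19, 11 over the list alone; adjusted p = 0.208 with an estimated correlation) and in anakinra livers (4 of 19, 8 over the list alone; 0.514).

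The counts against sham were 41 higher and 22 lower for EPO and 18 and 10 for anakinra at 24 h. They were 398 and 104 and 6 and 10 at 72 h, and 178 and 237 and 135 and 130 at 7 days. Of the anakinra calls at 7 days, 134 of 135 higher and 124 of 130 lower genes had the same sign in vehicle against sham livers, which share the sham arrays. Leaving out 1 array moved the counts as follows. At 24 h the EPO count of 63 was 20, 25, 41 and 31 without sham array 2, 3, 4 or 5 and 41, 18 and 24 without EPO array 1, 3 or 5. The anakinra count of 28 was 16, 6, 9 and 5 without sham array 1, 2, 3 or 5 and 14, 0 and 4 without anakinra array 1, 4 or 5. At 72 h the EPO count of 502 was 318 without sham array 2 and 279 without EPO array 2. The anakinra count of 16 was 6, 9 and 0 without sham array 2, 3 or 5 and 0, 0 and 7 without anakinra array 1, 3 or 4. At 7 days the EPO count of 415 was 245, 168 and 192 without sham array 1, 2 or 3 and 665, 199 and 147 without EPO array 2, 3 or 5. The anakinra count of 265 was 154, 57, 130 and 92 without sham array 1, 2, 3 or 5 and 96 and 69 without anakinra array 3 or 4.

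**Figure D4:**
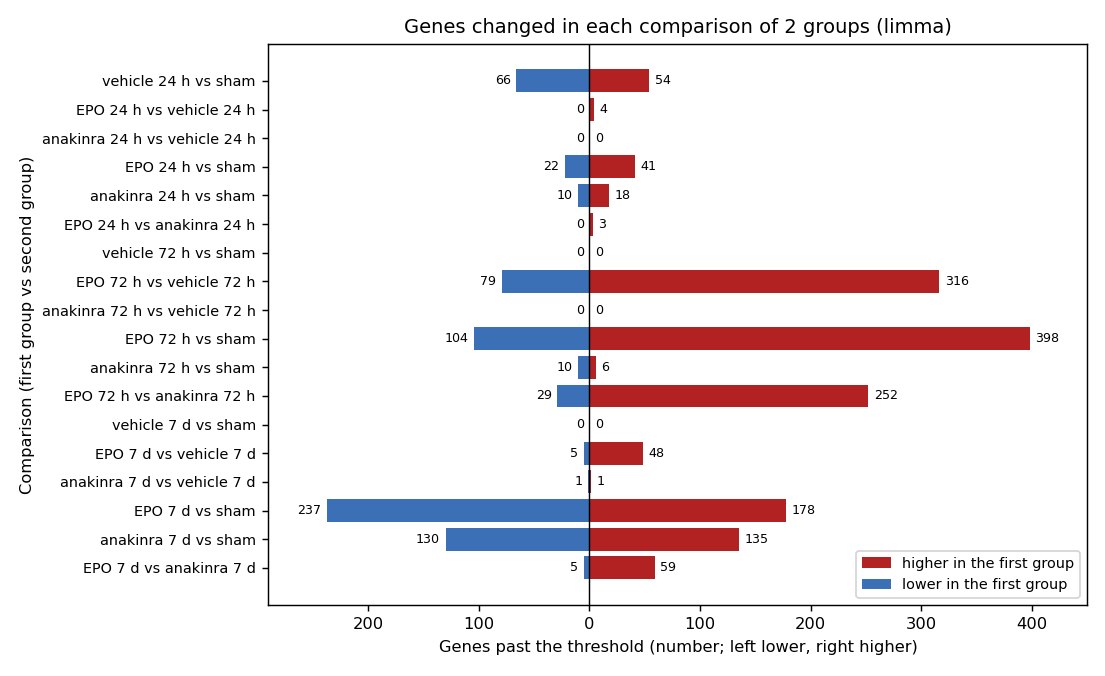
Number of genes past an adjusted p of 0.05 in limma (x axis) in each of the 18 comparisons of 2 groups (y axis); bars to the right are genes higher and bars to the left genes lower in the group named first. EPO against vehicle gave 316 higher and 79 lower genes at 72 h, and anakinra against vehicle gave 0 and 0.

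EPO was compared directly with anakinra at each time. At 24 h 3 genes were higher in EPO livers and 0 lower (245 at an unadjusted p under 0.05): Fgf23 (0.77), Tacr1, the substance P receptor (0.73), and Csf2rb (0.65), each with an adjusted p of 0.00978 and in 5 of 5 arrays. At 72 h Alox15 (4.29), Ahsp (3.92) and Slc4a1 (3.19) were highest and Hamp (-3.92) lowest, followed by Cyp2b2, Slc13a4 (-0.85), Dhcr7 of cholesterol synthesis (-0.77) and Dhrs7l1 (-0.74). There 20 of 24 erythroid transcripts, 18 of 46 cell cycle genes and 8 of 21 neutrophil markers were higher (21, 31 and 11 over the list alone), with an adjusted p = 0.000241, 0.000666 and 0.00943 with an estimated correlation. At 7 days Alox15 (4.67) and Hamp (-5.29) were again at the ends, and 17 of 24 erythroid transcripts were higher (22 over the list alone; adjusted p = 0.000361 with an estimated correlation). The numbers of genes higher and lower were 252 and 29 at 72 h and 59 and 5 at 7 days. The total was 0 without EPO array 1 or 5 at 24 h, 177 without anakinra array 3 at 72 h and 39 without EPO array 1 at 7 days.

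Across the 14506 genes, the log2 effects of EPO and of anakinra against the same vehicle arrays correlated at r = 0.73, 0.50 and 0.33 at the 3 times. The effects of injury correlated at r = 0.79 between 24 h and 72 h, 0.62 between 24 h and 7 days and 0.76 between 72 h and 7 days. These correlations are across genes, which are not independent replicates. Effects that share their control arrays correlate by construction: simulated effects without any change gave r = 0.51 on average (SD 0.19 over 100 draws). With the control arrays split so that the effects shared none, r averaged 0.09 (-0.26 to 0.29 over 20 splits), 0.16 (-0.18 to 0.40) and -0.08 (-0.43 to 0.17) for the drugs. For injury it averaged 0.58 (0.52 to 0.65), 0.39 (0.25 to 0.52) and 0.49 (0.37 to 0.60). Without vehicle array 3 at 7 days the injury correlations that involve that time were 0.42 and 0.49.

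Over the 34 lists and the 9 main comparisons, camera calls with an estimated correlation were left for 3 lists only: erythroid transcripts (EPO at 72 h and 7 days), cell cycle genes and Kupffer cell markers (EPO at 72 h). The numbers of main comparisons with a call at the preset correlation and, after them, the smallest adjusted p with an estimated correlation were 6 and 0.293 for P450 genes, 4 and 0.517 for other phase I enzymes and 6 and 0.121 for conjugating enzymes. For transport and its regulation they were 1 and 0.252 for uptake transporters, 2 and 0.263 for efflux transporters, 0 and 0.659 for xenobiotic and liver transcription regulators, and 0 and 0.605 for bile acid genes. For inflammation they were 3 and 0.111 for positive acute phase proteins, 2 and 0.558 for negative ones, 1 and 0.199 for targets of IL-1, TNF and NF-kB, 5 and 0.481 for interferon response, 2 and 0.122 for neutrophil markers and 2 and 0.719 for lymphocyte markers. For signalling they were 2 and 0.481 for iron and BMP-SMAD genes and 1 and 0.0704 for STAT5 genes. They were 4 and 0.226 for male-biased and 2 and 0.153 for female-biased liver genes, 0 and 0.558 for the clock, and 2 and 0.484 for glucocorticoid response.

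For metabolism and stress they were 4 and 0.441 for fatty acid oxidation, 5 and 0.319 for fatty acid synthesis and 3 and 0.170 for cholesterol synthesis, and 3 and 0.579 for ER stress, 3 and 0.115 for heat shock proteins. They were 6 and 0.170 for oxidative stress and NRF2 targets, 6 and 0.455 for ribosomal proteins and 7 and 0.170 for oxidative phosphorylation. For other cell types and tissues they were 3 and 0.0823 for liver endothelium, 0 and 0.455 for stellate cells, 0 and 0.757 for cholangiocytes, and 6 and 0.481 for pancreas, muscle, adipose and mesothelium markers. The median, mean and test of a called list had the same sign in all 18 comparisons but for the iron list in EPO against sham livers at 24 h, called higher with a median of 0.04 and a mean of -0.01.

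**Figure D5:**
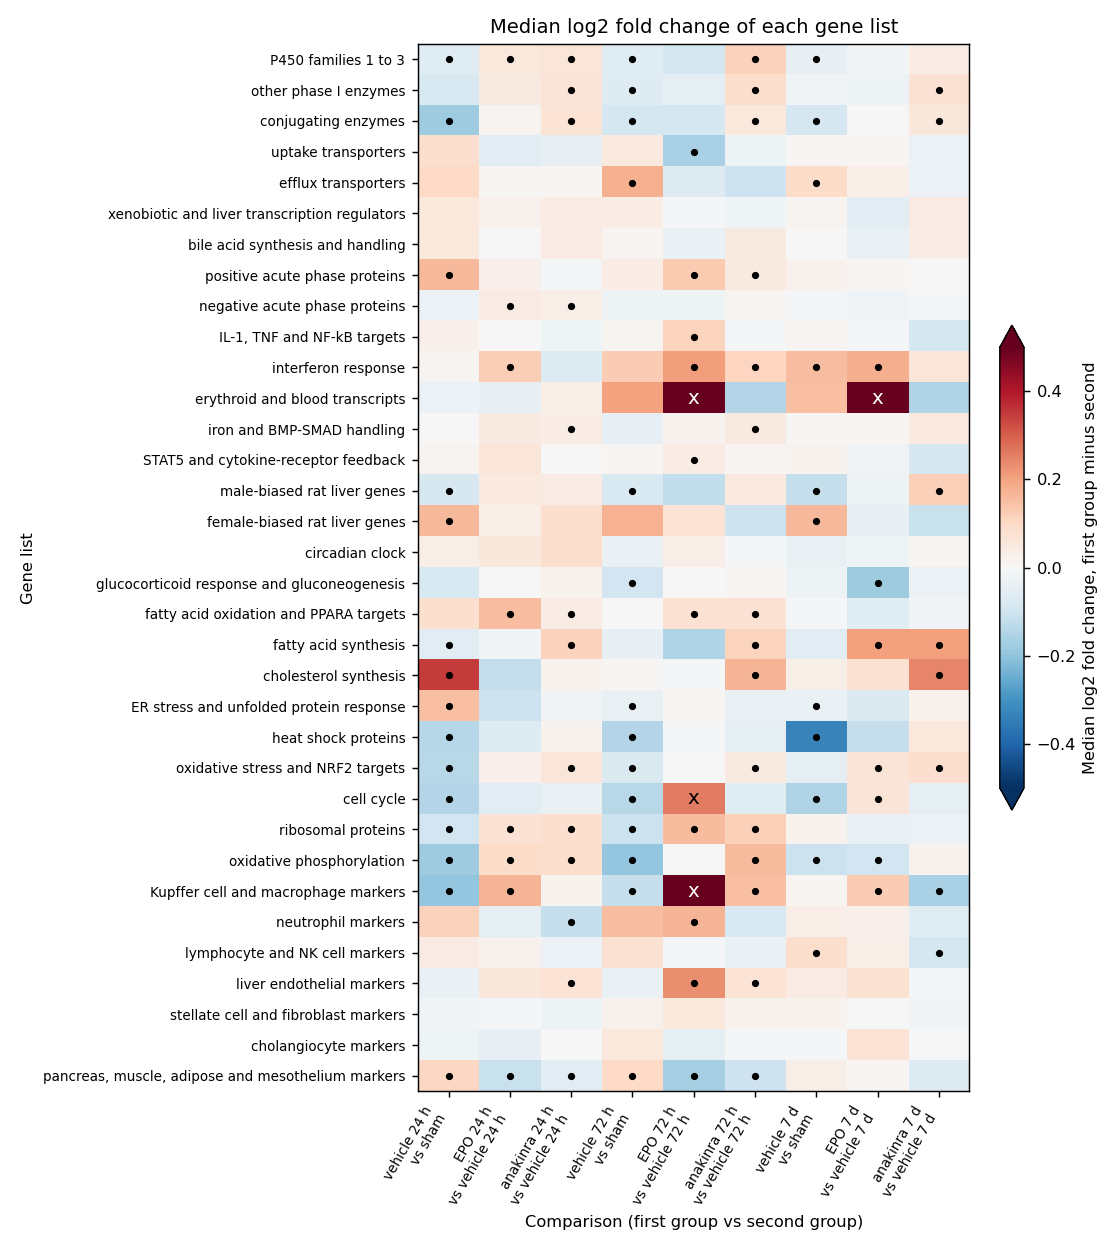
Median log2 difference of the measured members of each of the 34 gene lists (y axis) in the 9 main comparisons (x axis), coloured from blue (lower in the group named first) to red (higher), with values beyond 0.5 at the end of the scale. Dots are camera calls at the preset correlation and crosses are calls that also held with an estimated correlation: the erythroid list at 72 h and 7 days and the cell cycle and Kupffer cell lists at 72 h, all for EPO against vehicle.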

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

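The tests of the 3 patterns weighed here were chosen after the data were seen, the one with array standard deviation as a covariate at 72 h before its own outcome was; the splits of the samples were listed in advance.

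Over 34 list means and 29 genes in 10 groups, 29 of 630 groups of 5 held an array far from the other 4 by Dixon's test, 4.60%, and chance gives about 1 in 20. In 5 of these 29 cases the array was a narrow one, vehicle array 2 at 72 h being apart in 2 of them. The narrow EPO array 3 at 7 days was apart in none. Among list means the arrays apart were, in log2, xenobiotic regulators in EPO array 4 at 72 h (9.20), bile acid genes in vehicle array 2 at 7 days (10.88), positive acute phase proteins in anakinra array 2 at 24 h (10.87), negative ones in anakinra array 5 at 72 h (12.57) and iron genes in vehicle array 1 at 24 h (10.15). STAT5 genes were apart in vehicle array 2 at 24 h (8.74) and EPO array 5 at 72 h (8.84), glucocorticoid response in EPO array 1 at 24 h (10.53) and fatty acid synthesis in anakinra array 1 at 7 days (10.17). Cholesterol synthesis was apart in vehicle array 2 at 72 h (9.47), vehicle array 3 at 7 days (9.11) and anakinra array 5 at 72 h (9.70). ER stress was apart in vehicle array 3 at 24 h (9.57) and EPO array 3 at 72 h (9.92), heat shock proteins in vehicle array 2 at 72 h (9.35) and cell cycle genes in EPO array 4 at 24 h (5.99).

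Among single genes they were Cyp2b2 in EPO array 4 at 24 h (11.87), Cyp2c11 in vehicle array 5 at 24 h (13.25), Cyp3a18 in anakinra array 4 at 72 h (12.88), Slco1b2 in EPO array 4 at 72 h (11.99) and Abcb1a in EPO array 2 at 24 h (7.18). Abcb1b was apart in vehicle array 5 (7.61) and anakinra array 3 (6.72) at 72 h, Abcb11 in vehicle array 4 at 7 days (12.05), Abcc2 in sham array 3 (12.35) and Nr1i2 in EPO array 1 at 7 days (10.12). Orm1 was apart in anakinra array 2 at 7 days (12.72), and Lcn2 in EPO array 5 at 24 h (11.78) and anakinra array 2 at 7 days (10.21).

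The effect of EPO differed between times in 31 genes by the interaction test of limma. The 10 with the smallest adjusted p were Rhag (7.04e-06), Mmp8 and Tacr1 (7.42e-05 each), Csf2rb and Rrm2 (0.000450 each), Ngp (0.000581), Fgf23 (0.000893), Hamp (0.00120), Cd52 (0.00366) and Slc25a37 (0.00369), with the effects given above. Probes without a single gene symbol, 13904 in all and outside the comparisons, also passed when tested apart, in 3 of the 9 main comparisons: 16 in vehicle against sham livers at 24 h (6 higher), 113 in EPO against vehicle livers at 72 h (72 higher) and 12 at 7 days (11 higher).

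Other splits of the same 10 arrays, 100 drawn of 126 and the real one included, tested whether chance can be excluded for each count of genes. The rule was not adjusted for the number of counts. Some small counts that met it fell to 0 with 1 array left out: EPO against vehicle, EPO against anakinra and anakinra against sham at 24 h, and anakinra against sham at 72 h. For these the rule cannot settle the matter, and below the word excluded, said of chance, means only that the rule was met. It can be excluded where under 5 of 100 splits gave as many genes: vehicle against sham at 24 h (1 split; 120 genes, highest other split 4), EPO against vehicle at 24 h (1; 4, highest other 2), EPO against sham at 24 h (1; 63, 1), 72 h (1; 502, 213) and 7 days (1; 415, 6), and anakinra against sham at 24 h (1; 28, 2), 72 h (1; 16, 0) and 7 days (1; 265, 4). The same held for EPO against anakinra at 24 h (1; 3, 0), 72 h (2; 281, 292) and 7 days (1; 64, 20). It cannot be excluded for EPO against vehicle at 72 h (5 splits; 395, 3531) and 7 days (8; 53, 3104), for anakinra against vehicle at 7 days (5; 2, 303), or for the tests over time of vehicle (15; 10, 4202) and of the EPO interaction (9; 31, 3160). These verdicts are on counts, and not every split is free of the EPO effect. The one with 3531 genes put only EPO array 1 with vehicle arrays 1, 2, 3 and 5. At 7 days the split with 3104 genes, which points to a structure of the samples, called 0 with array standard deviation as a covariate, and the real one 69 (3 of 100 splits as many, highest other 606). At 72 h 4 of 100 splits gave as many with that covariate. With it the rule of under 5 splits was therefore met for EPO against vehicle at 72 h and 7 days, in a fit chosen after the data were seen. Single genes were not put to this test. At 7 days Hamp and Alox15 passed in limma (adjusted p = 6.58e-13 and 1.91e-06), each with 5 of 5 arrays apart. Where limma called 0 genes all 100 splits gave as many: vehicle against sham at 72 h (1757 at an unadjusted p under 0.05; highest other 1) and 7 days (946; 0), anakinra against vehicle at 24 h (616; 5) and 72 h (1546; 28), and the anakinra interaction (402; 484), with 5, 2, 0, 0 and 0 genes under array weights. For gene lists it cannot be excluded in any main comparison, with 9, 25 and 43 splits calling as many lists for vehicle against sham at the 3 times (15, 14 and 11 lists; highest other 18, 19 and 22), 51, 39 and 66 for EPO (8, 13 and 8; 17, 20 and 21) and 11, 22 and 67 for anakinra (13, 15 and 8; 18, 20 and 16).

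The first pattern weighed is the rise of erythroid transcripts in EPO livers, with list means 1.30 above vehicle at 72 h (95% interval 0.89 to 1.72) and 1.13 at 7 days (0.72 to 1.54), against 0.09 at 24 h (-0.32 to 0.50). Without the narrow arrays the difference at 72 h was 1.28 (0.79 to 1.77), and the lowest EPO array (8.41) lay above the highest vehicle array (8.06), which argues against the narrow arrays as its cause. More residual blood of unchanged makeup was weighed with markers of other blood cells. S100a8 and S100a9, neutrophil transcripts, differed by 1.04 at 72 h (0.73 to 1.34) and -0.11 at 7 days (-0.42 to 0.20). Lymphocyte markers differed by 0.07 (-0.04 to 0.19, with Il7r, Gzma and Nkg7 higher by 0.97, 0.61 and 0.53) and 0.04 (-0.08 to 0.15). Both means (5.06 and 6.51 in vehicle livers at 7 days) lay below the median gene (7.24), where a change can be hidden. The S100a8 and S100a9 mean did rise at 72 h from 4.99 in vehicle livers, so this level does not hide every rise. At 7 days neither mean rose clearly while the erythroid transcripts did. How much such a level shrinks a change was not tested, so this explanation cannot be told apart from a change in red cells. Circulating reticulocytes and dividing precursors in the liver cannot be told apart, since the cell cycle list differed by 0.054 (-0.05 to 0.16) at 7 days but by 0.29 (0.18 to 0.39) at 72 h, and the arrays hold no count of cells. The list was called lower in vehicle than in sham livers at 72 h. Against sham the EPO livers at 72 h differed by 0.11 (-0.00 to 0.21), so the 0.29 can also be a return towards sham. An action of EPO on red cell formation, the biological explanation that the design gives, stays open beside these.

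The second pattern is that another split of the EPO and vehicle arrays at 72 h called 3531 genes, several times the 395 of the real one, which points to a structure of the samples besides the drug. That split set EPO array 1 and vehicle arrays 1, 2, 3 and 5 (mean standard deviation 2.07) against vehicle array 4 and EPO arrays 2 to 5 (2.13). With array standard deviation as a covariate it called 392 genes in place of 3531, and the real split 330 (4 of 100 splits as many, highest other 646). That split still sets EPO arrays 2 to 5 against vehicle arrays 1, 2, 3 and 5, so the 392 can hold the effect of EPO. The test therefore cannot decide whether array standard deviation was the whole cause of the larger count. A swap of EPO array 1 with vehicle array 4 is argued against by their erythroid means, 8.41 and 7.69, the first above every vehicle array and the second below every EPO array, and by their Hamp values, 7.60 and 13.16. No biological explanation was tested.

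The third pattern is the change of clock genes in vehicle livers at 24 h. Without the narrow array of that group alone, 3 of the 4 called members (Dbp, Per3 and Tef) were still called, at 1.67, 1.13 and 0.65, which argues against that array as the whole cause. Bmal1 lost its call (adjusted p = 0.0843, against 0.0364 with all arrays) as its difference went from -0.70 (SE 0.17) to -0.70 (SE 0.19), with 1 array fewer; without all 5 narrow arrays it was called (0.0451). Another time of day at collection than in sham cannot be told apart from an effect of injury, since times of day are not given in the sources used here. It could raise Dbp in all 3 groups taken at 24 h, and the smallest of their differences from sham was 0.60 (95% interval -0.08 to 1.29, EPO), an interval that holds both outcomes.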

How the results depend on the processing

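The fits without the narrow arrays and with array standard deviation as a covariate were chosen only after the data were seen, and the other alternatives were listed in advance.

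Of the 124 calls of named genes in the main comparisons none reversed its direction under the alternatives run. Of these calls 96 held without the narrow arrays (28 lost), 109 with array weights (15), 111 with the covariate (13), 111 with arrays shifted to a common median (13), 109 with a second quantile normalization (15), 120 with the replicate block (4), 119 with trend and robust eBayes (5) and 63 with only the groups compared (61). That last fit has fewer residual degrees of freedom and takes its variance from the compared groups alone. Some counts against sham rose in it, as given below, so fewer degrees of freedom are not the whole reason. The main model gives each gene the same variance in all groups, while spreads differed: the SD of Hamp was 1.45 in vehicle livers at 72 h and 0.16 in sham. Whether this moved the counts was not tested. With trend and robust eBayes and with the mean of all probes of a gene, every count of genes and lists stayed within 1.5 times of its value above. The cause was not tested for any change given below unless it is named.

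Comparisons are written here as vehicle, EPO or anakinra at a time against vehicle (V) or sham (S). With array weights the counts were 267 genes for vehicle 24 h against S, 23 for EPO 24 h against V, 404 and 280 for EPO and anakinra 24 h against S, 12 for EPO against anakinra at 24 h, 5 for vehicle 72 h against S, 1011 and 437 for EPO and anakinra 72 h against S, 532 for EPO against anakinra at 72 h, 2 for vehicle 7 days against S, 20 for anakinra 7 days against V, 875 and 1125 for EPO and anakinra 7 days against S, 62 for vehicle over time and 111 for the EPO interaction. The correlations were 0.264 for EPO and anakinra at 72 h and 0.570, 0.309 and 0.523 for injury at 24 and 72 h, 24 h and 7 days, and 72 h and 7 days.

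With array standard deviation as a covariate they were 2 for EPO 24 h against V, 107 and 44 for EPO and anakinra 24 h against S, 836 and 41 at 72 h, 424 for EPO against anakinra at 72 h, 21 for anakinra 7 days against V, 608 for anakinra 7 days against S, 26 for vehicle over time and 51 for the EPO interaction. Lists called were 6, 7 and 5 for anakinra against V at the 3 times and 22 for EPO 72 h, and the drug correlation at 72 h was 0.234. Without the narrow arrays they were 79 for vehicle 24 h against S, 2 for EPO 24 h against V, 97 and 45 for EPO and anakinra 24 h against S, 29 for anakinra 72 h and 577 for anakinra 7 days against S, 0 for anakinra 7 days against V and 20 for the EPO interaction. Lists were 8, 7 and 5 for anakinra against V, and the injury correlations 0.533 (24 and 72 h) and 0.422 (24 h and 7 days).

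With only the groups compared they were 48 for vehicle 24 h against S, 0 and 53 for EPO 24 h and 72 h against V, 163, 302 and 779 for EPO against S, 7 and 76 for EPO against anakinra at 24 h and 72 h, 130 and 694 for anakinra 72 h and 7 days against S, 0 for anakinra 7 days against V, 3 for vehicle over time and 13 for the EPO interaction. With a change of at least 1.5-fold required, which can only lower a count, they were 59 for vehicle 24 h against S, 30, 208 and 154 for EPO against S, 16, 10 and 83 for anakinra against S, 156 for EPO 72 h against V, 132 for EPO against anakinra at 72 h and 1 for anakinra 7 days against V.

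With arrays shifted to a common median they were 37 and 276 for EPO 24 h and 7 days against S, 3, 7 and 149 for anakinra against S, 2 for vehicle 72 h against S and 0 for anakinra 7 days against V. A second quantile normalization gave 2 and 2 for vehicle 72 h and 7 days against S, 0 for anakinra 7 days against V, 16 for vehicle over time, and 5 lists for vehicle 72 h and 6, 3 and 5 for anakinra. With all probes of the table they were 1 for EPO 24 h against V, 14 and 8 for anakinra 24 h and 72 h against S, 0 for anakinra 7 days against V, 6 for vehicle over time and 15 lists for EPO 24 h. With dim genes left out they were 1 for anakinra 7 days against V, 18 for the EPO interaction and 6 lists for anakinra 72 h. The replicate block gave 1 and 2 for vehicle 72 h and 7 days against S, 26 for anakinra 72 h against S and 0 for anakinra 7 days against V; the replicate numbers do not pair the animals.

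With the correlation estimated, the lists called were 0, 0 and 0 for vehicle against S, 0, 3 and 1 for EPO and 0, 0 and 0 for anakinra against V, and with fry 6, 1 and 0, 0, 9 and 1, and 0, 0 and 0. With the control arrays split, which removes the shared controls, the mean correlations over 20 splits were 0.0863, 0.156 and -0.0829 for the drugs, each with a range over the splits that holds 0, and 0.576, 0.391 and 0.490 for injury.

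With each array left out in turn, the counts ranged from 56 to 151 for vehicle 24 h against S, 0 to 5 at 72 h and 0 to 2 at 7 days. They ranged for EPO against V from 0 to 5, 205 to 1520 and 34 to 56, for anakinra against V from 0 to 0, 0 to 0 and 0 to 3, for EPO against S from 18 to 50, 279 to 681 and 147 to 665, and for anakinra against S from 0 to 36, 0 to 21 and 57 to 280. For EPO against anakinra they ranged from 0 to 4, 177 to 398 and 39 to 69, and for vehicle over time, the EPO interaction and the anakinra interaction from 4 to 23, 21 to 87 and 0 to 0. The arrays behind each change of over 1.5 times are named with the comparisons above. Lists called ranged from 12 to 17, 10 to 18 and 8 to 13 for vehicle against S, 7 to 11, 12 to 19 and 6 to 12 for EPO, and 7 to 14 (7 without vehicle array 3 at 24 h), 10 to 15 and 5 to 9 (5 without vehicle array 3 or 4 at 7 days) for anakinra. Correlations ranged from 0.557 to 0.815, 0.320 to 0.623 and 0.238 to 0.467 for the drugs and 0.621 to 0.813, 0.415 to 0.661 and 0.491 to 0.787 for injury, the last pair lowest without vehicle array 3 at 7 days.

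Background correction and a block for slide or scan date were not run, since scanner values and dates were not in the files used here. Signal over background limits these arrays: the table used here held no detection call, so a dim gene cannot be told from background, and probes of near-identical genes such as Cyp2b1 and Cyp2b2 or the globins can read each other's transcripts, which was not tested.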

Other observations

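The values of this part were chosen after the results were seen, and none of them was put to a test of an explanation.

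Hepcidin was low in some injured livers that had received no EPO. Among the 30 injured livers given vehicle or anakinra, Hamp was below 12, a level chosen after the values were seen, in 5, of which 4 were taken at 72 h: vehicle array 5 (Hamp 9.67, Alox15 10.15, mean of the erythroid list 8.02), anakinra array 4 (10.72, 11.21 and 8.34), vehicle array 3 (11.55, 10.75 and 8.06) and anakinra array 1 (11.61, 8.46 and 7.61). The fifth was anakinra array 3 at 7 days, whose Hamp of 11.998 lay just under that level and whose Alox15 was 6.88 and erythroid mean 7.21. In sham livers the lowest Hamp was 12.70, the highest Alox15 8.51 and the highest erythroid mean 7.70. In EPO livers at 72 h the lowest Alox15 was 11.97 and the lowest erythroid mean 8.41.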
